A study of Mus musculus with 6 samples.

How the data were processed

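The series holds bulk RNA sequencing of mouse left ventricular myocardium collected 9 days after transverse aortic constriction (TAC), an operation that narrows the aorta and loads the left ventricle with pressure. In all, 6 libraries were analysed, with 3 in a group labelled control and 3 in a group labelled Treg, which the series title describes as receiving regulatory T cells induced in culture. The labels do not state what the control group received, so a difference between the groups cannot be assigned to the cells as against the way they were given. Per the labels' protocols, total RNA was extracted from frozen tissue, and stranded mRNA libraries were sequenced as paired 101 bp reads. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 2.0.6, Cuffdiff 2.2.1 and the mouse build GRCm38 were used; the role of each tool, the counting options and the annotation release are not given in the sources used here.

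The authors deposited one table of 47729 Ensembl gene IDs with a value per library. These deposited values are estimated counts, not normalized, and between 46.5% and 50.0% of the values above 0 in a library are fractional. How the fractions arose is not given in the sources used here; if reads that fit several genes were divided among them, values of genes with a near-identical copy or a pseudogene are uncertain. Pseudogenes held 7.3% to 8.19% of each library's count, and genes encoded in the mitochondrion held 20.8% to 24.1%. The table has 6 further columns that match no sample listed for the series here, and these were not used. All rows name a gene. Symbols were taken from a GENCODE M21 name table (GRCm38), which matched 47224 IDs; 505 IDs had no match. Coordinates are those of GENCODE M21 on GRCm38, numbered from 1.

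Estimated counts were rounded to whole numbers, which changed no library's total by more than 0.0087%. Library totals lay between 28937253 and 29979080, so depth differed little between samples. No 2 libraries agreed within sampling noise: chi-square per degree of freedom was between 19.3 and 150.1 for the 15 pairs. The labels do not say outright that each library came from its own animal, and the p-values measure the spread between these libraries.

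The only contrast in the labels, Treg against control, was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (17365 genes), scaled with TMM factors, and tested two-sided with robust quasi-likelihood F tests without covariates and Benjamini-Hochberg adjustment at 0.05. The test had been chosen for raw counts, and the table turned out to hold estimated ones. Standard errors of log2 fold changes were derived as the fold change divided by the square root of F. Levels are given as CPM (counts scaled to the library total) on TMM-scaled library sizes. Gene lists for tissues, cell types and pathways (41 lists) were written from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 40 lists other than the sex-linked genes were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with an estimated correlation, fry (whether a list's genes move on balance in one direction) and a rank-based camera were alternatives.

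The naming rule took the 12 genes with the smallest p in each direction among those past the threshold or, with fewer than 5 past it, the 5 with the smallest p in each direction; predicted genes and mitochondrial or antigen receptor genes were left out. It added the 5 largest changes among genes past the threshold at a mean of at least 1 CPM, up to 4 members with the smallest p in each list described, and 16 genes of heart load, fibrosis and inflammation chosen whatever their values. Other genes are said to have been chosen afterwards.

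Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, edgeR's newer dispersion method, RLE and upper-quartile scaling, no filter and a filter at a mean of 1 CPM, removal of mitochondrially encoded genes, the replicate number as a block, an adjusted p of 0.1, a log2 fold change of at least 1, and leaving out each library in turn. Sample quality weights, protein-coding genes only, and the joint omission of control replicate 3 and Treg replicate 3 were added after seeing the data. The tests were checked on simulated counts drawn from the means, dispersions and library sizes of the 17365 genes in this comparison. With 100 genes changed 2-fold and 100 changed 4-fold (1 and 2 on the log2 scale), edgeR recovered 42% and 89% of them. None was in the wrong direction, and there were 15 false calls. Each simulated gene had the same dispersion in all libraries, so no simulated library stood apart as control replicate 3 does in the data. These recovery rates therefore need not hold for this comparison. Camera recovered a list shifted by 0.5 (adjusted p = 5.86e-15) and called 0 other lists. The genes were drawn independently of each other, so this does not show how often camera calls lists whose members move together. In the data the estimated correlation was 0.466 for interferon genes and 0.56 for collagens.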

Results

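Left ventricular myocardium was profiled by RNA sequencing 9 days after TAC in 3 libraries labelled control and 3 labelled Treg. The study's title frames the comparison as whether regulatory T cells made in culture lessen remodelling and fibrosis under pressure overload. Library totals were 29842787, 29815561 and 28937253 counts in the control group and 29841591, 29979080 and 29876847 in the Treg group. No unoperated hearts were analysed here, so every value below compares operated samples with each other. Y-linked transcripts were present in all 6 libraries (Ddx3y at 1746 to 3031 counts). Xist was low, at 10 counts in each control library and at 29, 32 and 16 in the Treg libraries. The cause of that difference was not tested.

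The control libraries differed from each other more than the Treg libraries did. Correlations of log2 CPM over all tested genes were 0.967 to 0.991 among 5 of the libraries, and 0.936 to 0.957 between control replicate 3 and the others. Control replicate 1 correlated at 0.9798 with control replicate 2 and at 0.9804 to 0.9827 with the Treg libraries. By this measure it lay no nearer to its own group than to the Treg libraries. The first principal component of the 500 most variable genes held 57.9% of their variance and separated control replicate 3, at −45.14, from the rest, at −8.12 to 19.71. In that library 406 genes lay over 2-fold above all other libraries and 751 over 2-fold below; in the other 5 libraries these numbers were 3 to 49 and 5 to 59. The genes that stood apart, described after their values were seen, included Arg1, an arginase of activated macrophages, at 41.27 CPM in control replicate 3 against 0.25 to 4.07 elsewhere, and Cx3cr1, the fractalkine receptor of resident macrophages, at 0.03 CPM against 6.06 to 11.59. Control replicate 2 was high for Mmp12, macrophage elastase, at 108.52 CPM against 0.67 to 3.30, and for Gpnmb, a lysosomal macrophage glycoprotein, at 144.49 CPM against 1.89 to 7.93. Neutrophil markers had a median 1.94 log2 units above their 6-library mean in control replicate 3, and erythroid genes had a median of −1.973 there. Treg replicate 3 held transcripts of atrial muscle: Myl7, the atrial myosin light chain, was at 1202 counts against 1 to 6 in the other libraries, and Sln, sarcolipin, at 398 against 0 to 3.

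**Figure D1:**
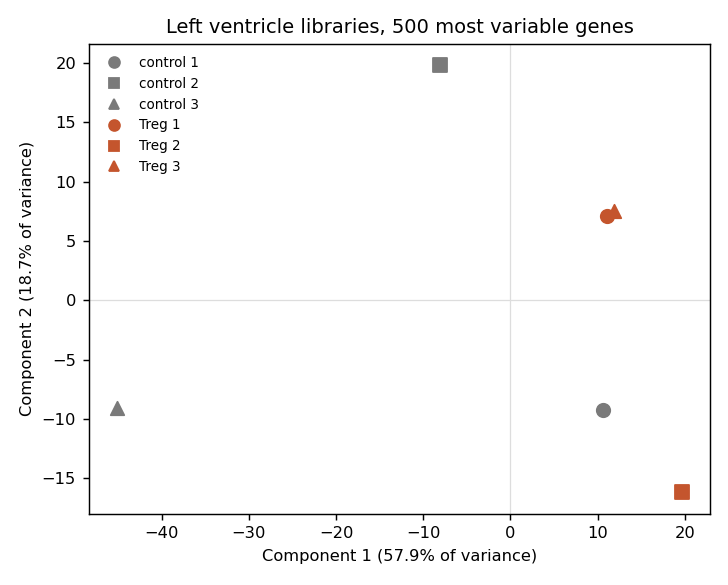
Principal components 1 and 2 of log2 CPM over the 500 most variable genes; each point is one library, grey for control and orange for Treg, with the replicate number as the symbol. Control replicate 3 sits at −45.14 on the first axis, while the other 5 libraries lie between −8.12 and 19.71.

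The genes that separated the groups most clearly were not the classical load or fibrosis markers. Among those with higher levels in the Treg libraries, Mylk4, a myosin light chain kinase family member (chromosome 13, 32700834 to 32783954), stood at 12.1 ± 4.14 CPM in control and 101 ± 17.4 in Treg (mean ± SD, n = 3, as throughout), a log2 fold change of 3.07 ± 0.29 (SE). Ces1d, a carboxylesterase that hydrolyses lipid (chromosome 8, 93166068 to 93197838), stood at 2.05 ± 1.10 and 37.8 ± 10.1 CPM, a log2 fold change of 4.20. Penk, the enkephalin precursor, had a log2 fold change of 2.68, Efnb3, an ephrin, 2.40, and the ephrin receptor gene Epha4, 1.22. In the other direction, Nrip3 (chromosome 7, 109758055 to 109782025) stood at 12.9 ± 1.40 CPM in control and 1.60 ± 0.555 in Treg, a log2 fold change of −3.01 ± 0.28. Atxn10 went from 197 ± 19.8 to 78.6 ± 6.41 CPM (−1.33), the clock gene Npas2 from 3.82 ± 0.438 to 1.06 ± 0.108 (−1.84), the enolase gene Eno2 had −1.56 and Maged2 −0.98. For all 10 genes every Treg library lay to the same side of every control library.

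None of these 10 genes passed the threshold: by edgeR's quasi-likelihood test, 0 of 17365 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.0847. At an adjusted p under 0.1 there were 44 genes higher and 38 lower in the Treg libraries. At an unadjusted p under 0.05 there were 2873 genes, 1430 higher and 1443 lower, where 868 are expected without any difference. The groups did not overlap at 25.4% of genes, where random labels give 10% on average. Genes move together, so a single split can depart from that average, and this share was not computed for the other splits. The number of genes past the threshold depended on the tool and on one library. DESeq2 called 650 genes, 322 higher and 328 lower and among them all 10 named here, while limma-voom and edgeR's newer dispersion method called 0 (2816 and 2925 at unadjusted p under 0.05). Without control replicate 3, edgeR called 230 genes, 119 higher and 111 lower, including 9 of the 10 (Efnb3 had an adjusted p of 0.0651); all 230 had the same sign in the comparison of all 6 libraries.

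**Figure D2:**
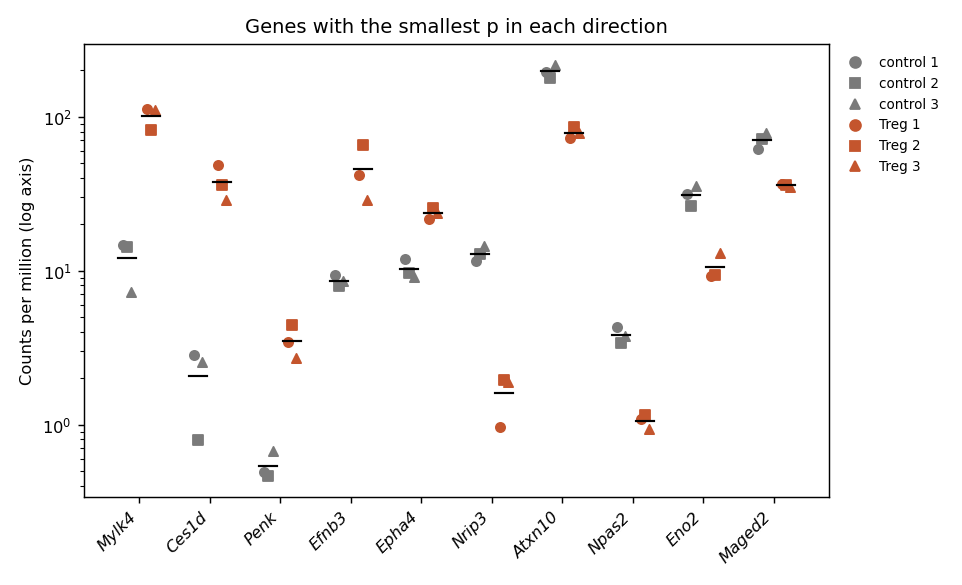
CPM on a log axis for the 5 genes with the smallest p in each direction; points are libraries (grey control, orange Treg, symbol by replicate number) and black bars are group means. The groups do not overlap at any of the 10 genes, with Mylk4 at 12.1 against 101 CPM and Nrip3 at 12.9 against 1.60 CPM as group means.

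Markers of cardiac load were mixed. Nppb, the B-type natriuretic peptide released under wall stress, stood at 662 ± 60.9 CPM in control and 353 ± 100.3 in Treg, a log2 fold change of −0.91 ± 0.22 with edgeR's adjusted p = 0.17 (DESeq2 adjusted p = 0.0062), lower in 3 of 3 Treg libraries than in any control. Nppa, the atrial natriuretic peptide, stood at 820 ± 603 and 705 ± 170 CPM (−0.22, edgeR adjusted p = 0.862), with the highest Treg value in the library that held atrial transcripts. Myh7, the slow myosin heavy chain that mouse hearts re-express under load, stood at 2558 ± 1128 CPM in control and 4822 ± 506 in Treg (0.91 ± 0.32, edgeR adjusted p = 0.252), opposite in sign to Nppb. Myh6, the adult myosin, had 0.19 and Acta1, skeletal actin, −0.38 (edgeR adjusted p = 0.73 and 0.546). Without control replicate 1, Nppa had 0.46 and Acta1 −0.11; without control replicate 3, Nppa had −0.66, Acta1 −0.66 and Myh6 −0.02. The list of hypertrophy and fetal cardiac genes, of which 24 were tested, ranked lower in the Treg libraries (camera adjusted p = 0.0182; adjusted p = 0.703 with an estimated correlation), with a median log2 fold change of −0.38. By edgeR 0 members passed over all genes and 4 were lower adjusted over the list alone: Fhl1, a LIM protein of the stretched sarcomere (−1.68), Uchl1 (−1.57), Nmrk2, a nicotinamide riboside kinase (−1.77), and Nppb. Without control replicate 3, Fhl1 and Uchl1 passed over all genes (edgeR adjusted p = 0.0426 and 0.0162). The list no longer passed without control replicate 1, control replicate 2 or Treg replicate 1 (camera adjusted p = 0.108, 0.0886 and 0.0596). Its median was −0.58 without control replicate 3 and −0.22 without Treg replicate 1.

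The comparison bears most directly on fibrosis through the matrix genes. The main fibrillar collagens overlapped between the groups: Col1a1 stood at 824 ± 324 CPM in control and 625 ± 287 in Treg (−0.40, edgeR adjusted p = 0.617) and Col3a1 at 2210 ± 571 and 1664 ± 727 (−0.41, edgeR adjusted p = 0.578). Postn, periostin, the marker of activated cardiac fibroblasts, had −0.53 (0.463), Ccn2, a TGF-beta induced matrix protein, −0.625 (edgeR adjusted p = 0.285), and Tgfb1 −0.17 (0.518). These values moved with single libraries: Col1a1, Col3a1 and Postn had −0.04, −0.21 and −0.17 without control replicate 2. Col1a1 and Col3a1 had −0.12 and −0.09 without Treg replicate 2 and −0.79 and −0.70 without Treg replicate 3, and Col1a1 and Postn had −0.60 and −0.82 without control replicate 3. The collagen list as a whole, 19 genes, ranked lower (camera adjusted p = 0.0182; adjusted p = 0.866 with an estimated correlation; median −0.36), with 15 of 19 fold changes below 0. By edgeR 0 passed over all genes and 2 were lower adjusted over the list alone, Col5a3, at 71.2 ± 8.35 and 30.4 ± 5.14 CPM (−1.23), and Col4a2, a basement membrane chain (−0.72). Treg replicate 2 lay lowest, with a list median of −0.626, and Treg replicate 3, at 0.315, lay above 2 of the 3 controls. The list's camera adjusted p was 0.06, 0.256 and 0.294 without control replicate 1, control replicate 2 and Treg replicate 2, and 2.77e-05 without control replicate 3. Its median was −0.04 without control replicate 2, −0.09 without Treg replicate 2 and −0.62 without Treg replicate 3.

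Genes for matrix proteases and their inhibitors ranked lower in the Treg libraries (29 genes; camera adjusted p = 0.000111; adjusted p = 0.637 with an estimated correlation; median −0.67), and 26 of 29 had a fold change below 0. By edgeR 0 passed over all genes and 3 were lower adjusted over the list alone. Mmp14, the membrane-bound collagenase, stood at 85.3 ± 9.67 CPM in control and 39.4 ± 7.22 in Treg (−1.11), Adamts4, an aggrecanase, at 8.82 ± 5.67 and 1.08 ± 0.282 (−3.02), and Plat, tissue plasminogen activator, at 37.0 ± 11.7 and 16.8 ± 1.76 (−1.14). All 3 passed over all genes when control replicate 3 was left out (edgeR adjusted p = 0.0393, 0.0237 and 0.0315). Matrix glycoproteins and crosslinking enzymes missed the threshold (32 genes; camera adjusted p = 0.0501, and 0.88 with an estimated correlation) but passed with RLE scaling (0.0499), protein-coding genes only (0.0487) and sample quality weights (0.0036), with 4 members lower adjusted over the list alone by edgeR, led by Mfap5, a microfibril protein (−0.87), and Lox, lysyl oxidase, at 202 ± 84.5 and 54.5 ± 19.6 CPM (−1.89). Activated fibroblast markers did not pass (camera adjusted p = 0.172, with Tnfrsf12a −1.39 and Ckap4 −0.65) but did with sample quality weights (0.00439). The TGF-beta list did not pass (camera adjusted p = 0.541, with Tgfb2 −0.76 and Ltbp1 0.39). With those weights and an estimated correlation, the activated fibroblast and matrix glycoprotein lists had 0.7 and 0.738. For matrix glycoproteins an estimated correlation gave 0.88 with RLE scaling and 0.869 with protein-coding genes only. The matrix glycoprotein and activated fibroblast lists ranked lower without control replicate 3 (camera adjusted p = 5e-04 and 0.000233; adjusted p = 0.68 and 0.665 with an estimated correlation) and without Treg replicate 3 (0.000348 and 0.0149; 0.526 and 0.622 with an estimated correlation).

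Interferon response genes had the smallest p of any list, ranking higher in the Treg libraries (camera adjusted p = 2.15e-13; adjusted p = 0.637 with an estimated correlation). All 38 tested members had a fold change above 0, with a median of 0.90, and in 21 of them every Treg library lay above every control. By edgeR 0 passed over all genes and 12 were higher adjusted over the list alone. Oas2, an antiviral oligoadenylate synthetase, stood at 3.80 ± 1.44 CPM in control and 11.6 ± 2.49 in Treg (1.61 ± 0.31), the guanylate-binding protein gene Gbp5 at 3.13 ± 0.684 and 6.88 ± 1.02 (1.14), and the immunity-related GTPase genes Iigp1 and Igtp had 1.08 and 1.06. Treg replicate 2, with a list median of 0.021 against the 6-library mean, lay much closer to the controls (−0.491 to −0.150) than Treg replicates 1 and 3 (0.479 and 0.694).

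Genes for MHC class II antigen presentation also ranked higher (11 genes; camera adjusted p = 0.000151; adjusted p = 0.637 with an estimated correlation; median 1.51). By edgeR 0 passed over all genes and 4 were higher adjusted over the list alone: H2-Ab1 (2.06), H2-Aa at 4.62 ± 4.09 and 21.1 ± 6.53 CPM, H2-Eb1 (2.27), and the invariant chain Cd74 at 11.2 ± 10.8 and 55.8 ± 14.8 CPM (2.31). Control replicate 3 was lowest, with a list median of −2.271, and leaving it out moved the list's median log2 fold change from 1.51 to 0.97 (camera adjusted p = 0.000156). Mast cell and dendritic cell markers ranked higher (12 genes; camera adjusted p = 0.00721; adjusted p = 0.637 with an estimated correlation; median 0.53), with 4 members higher adjusted over the list alone by edgeR and 0 over all genes. These were Mcpt4, a mast cell protease, at 0.113 ± 0.0495 and 0.645 ± 0.103 CPM, Cd209a, a dendritic cell lectin, at 0.162 ± 0.200 and 1.05 ± 0.167, Flt3 and Tpsb2, all near or below 1 CPM; among genes with a mean of at least 1 CPM the list did not pass (camera adjusted p = 0.558). Its median was 1.02, 0.87 and 0.94 without control replicate 1, control replicate 2 and Treg replicate 2. B cell markers ranked higher (11 genes; camera adjusted p = 0.038; adjusted p = 0.789 with an estimated correlation; median 0.555), with 0 members past either adjustment and Mzb1, at 1.28, having the smallest p. That call rested on control replicate 3, whose list median was −1.84; without it the camera adjusted p was 0.706, and without Treg replicate 1 it was 0.0692. It was 0.12 with ranks, 0.103 with protein-coding genes only and 0.22 with sample quality weights, and the median was 0.04 without control replicate 3, 0.31 without Treg replicate 1 and 1.08 without control replicate 1.

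**Figure D3:**
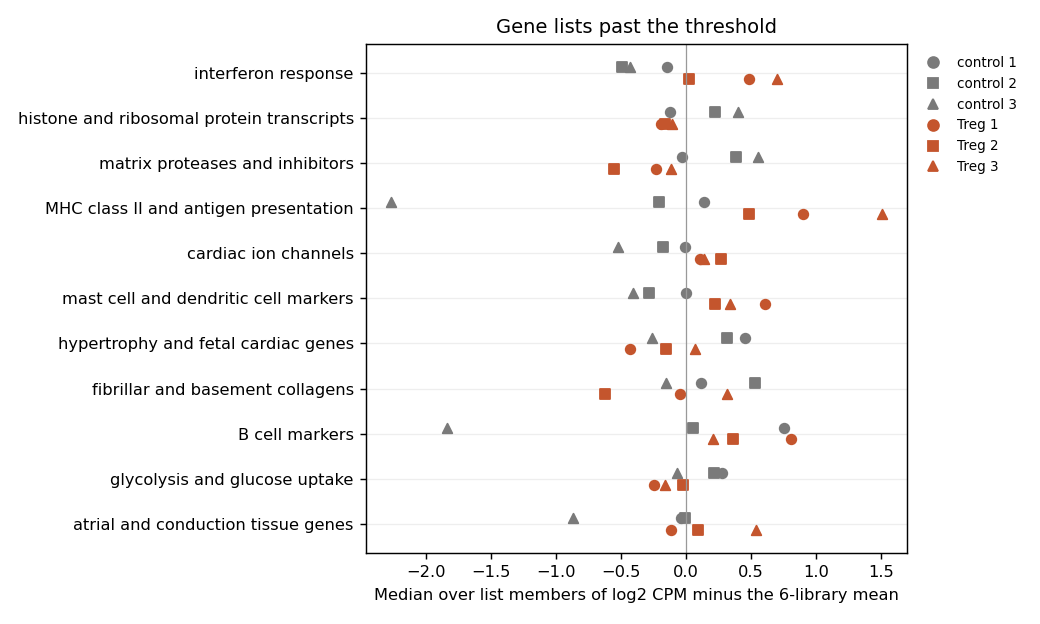
For each of the 11 lists past the camera threshold, the median over members of log2 CPM minus the 6-library mean, in log2 units, for each library (grey control, orange Treg, symbol by replicate number). Class II genes in control replicate 3 lie at −2.271, and collagens in Treg replicates 2 and 3 lie at −0.626 and 0.315, on either side of 0.

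Transcripts of the transferred cell type were scarce. Foxp3, the defining transcription factor of regulatory T cells, stood at 1.61 ± 0.161 CPM in control and 1.65 ± 0.125 in Treg (42 to 56 counts per library; log2 fold change 0.04 ± 0.22, edgeR adjusted p = 0.939). Il10 was at 0 to 2 counts in every library and Areg at 0 to 8, too few to test. The regulatory T cell list did not pass (14 of 24 genes tested; camera adjusted p = 0.946, direction lower, median 0.14 and mean 0.02, the median −0.04 without control replicate 2 to 0.10 without Treg replicate 2 over the 6 omissions), and its 1 member past the list-alone adjustment by edgeR was Nt5e, the ectonucleotidase CD73, which was lower (−0.92); 0 passed over all genes. Il2ra, the high-affinity IL-2 receptor chain, had 1.69 (edgeR adjusted p = 0.235). T cell and NK cell markers did not pass (9 of 31 tested; camera adjusted p = 0.546, direction higher, median 0.01 and mean −0.43, the median −0.22 without Treg replicate 1 to 0.41 without control replicate 2). Cd3e was at 82, 36 and 465 counts in the controls and 12 to 16 in the Treg libraries, while Cd3d, its partner in the T cell receptor complex, was at 0 to 3 counts in all libraries. Foxp3 lay above Cd3d and the T cell receptor gene Trac (0 to 13 counts) in every library. The source of its counts was not tested, so they cannot be read as the number of regulatory T cells.

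Macrophage and cytokine genes varied mainly between the control libraries. The macrophage list did not pass (26 genes; camera adjusted p = 0.946, and 0.038, lower, without control replicate 1, where an estimated correlation gave 0.803), and pan-macrophage genes were close between groups, with C1qa at 0.17 and Csf1r at 0.24. Spp1, osteopontin, stood at 238 ± 255 and 25.5 ± 11.5 CPM (−3.22, edgeR adjusted p = 0.215) and Lgals3, galectin 3, at 43.4 ± 40.0 and 8.51 ± 1.81 (−2.35, edgeR adjusted p = 0.218). Without control replicate 2 these fold changes were −1.91 and −1.32. Ccl2, the monocyte chemoattractant, stood at 26.7 ± 33.0 and 3.81 ± 2.81 CPM (−2.81, edgeR adjusted p = 0.284), moving to −1.07 without control replicate 3, and Il6 at 2.75 ± 3.17 and 0.583 ± 0.309 (−2.23, moving to −0.66). Il1b had 0.53 (edgeR adjusted p = 0.659), with 1.45 without control replicate 3 and 0.09 without Treg replicate 3. The cytokine and chemokine list did not pass (31 genes; camera adjusted p = 0.45), with 1 member, Ccl3, lower adjusted over the list alone by edgeR (−2.99) and Ccl21a at 1.22.

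Cardiac ion channel genes ranked higher in the Treg libraries (26 genes; camera adjusted p = 0.000151; adjusted p = 0.637 with an estimated correlation; median 0.36), with 21 of 26 fold changes above 0. By edgeR 0 passed over all genes and 6 were higher adjusted over the list alone. Kcnj3, a subunit of the acetylcholine-gated potassium channel, stood at 14.7 ± 2.41 and 33.9 ± 3.78 CPM (1.21), Kcnv2 at 0.538 ± 0.425 and 3.51 ± 0.691 (2.70), Cacna1s had 1.22 and Kcnj5 0.81; Kcnj3 and Kcnv2 passed over all genes without control replicate 3 (edgeR adjusted p = 0.0199 and 0.033). The atrial and conduction list, which also holds the channel genes Kcnj3 and Hcn4, ranked higher (12 genes; camera adjusted p = 0.0427; adjusted p = 0.703 with an estimated correlation). Its members Kcnj3, Stard10 (1.33) and Hcn4 (1.02) were higher adjusted over the list alone by edgeR, 0 passed over all genes, and Myl4 (2.80) was high only in Treg replicate 3. The list's camera adjusted p was 0.0561, 0.438 and 0.164 without control replicate 2, control replicate 3 and Treg replicate 3. It was 0.0697 with ranks, 0.0512 with protein-coding genes only and 0.295 with sample quality weights. The list's median, 0.38, was −0.12 without Treg replicate 3, 0.22 without control replicate 3, and 0.62 and 0.60 without control replicate 1 and Treg replicate 1.

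Glycolysis genes ranked lower (25 genes; camera adjusted p = 0.038; adjusted p = 0.703 with an estimated correlation; median −0.38), with 6 members lower and 1 higher adjusted over the list alone by edgeR and 0 over all genes. Pgk1, phosphoglycerate kinase, stood at 751 ± 65.9 and 396 ± 28.1 CPM (−0.92), a value that is uncertain if reads are shared with processed copies such as Pgk1-rs7; the lactate exporter gene Slc16a3 had −1.59, Eno1 −1.04, and Pfkfb1, which sets the level of a glycolytic activator, 1.22. The list did not pass without control replicate 1, control replicate 2 or Treg replicate 1 (camera adjusted p = 0.156, 0.0907 and 0.0596), or with ranks (0.0991). Histone and ribosomal protein transcripts ranked lower (25 genes; camera adjusted p = 5.81e-05; adjusted p = 0.655 with an estimated correlation; median −0.35), with 5 lower and 1 higher adjusted over the list alone by edgeR; without control replicate 3 the median was −0.215. Those named by the rule were Hist1h1c (−0.56), Rpl3 (−0.86), Rps28 (−0.61) and Hist1h4i (0.87), and ribosomal protein genes have many processed copies that can share reads. In all, 6 lists ranked higher and 5 lower of 40. With an estimated correlation, and by fry's test for 1 shared direction, 0 lists passed. Fry's p for changes in either direction was not adjusted over the lists and not used for calls. It was smallest for clock genes (0.000118), followed by glycolysis genes (0.000296) and complement and coagulation genes (0.000298). The preset test is generous here: each of the other 9 ways of splitting the same 6 libraries into 3 and 3 called 12 to 21 lists.

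Clock genes differed in both directions. Their list did not pass (19 genes, camera adjusted p = 0.39). With sample quality weights it ranked higher (camera adjusted p = 0.0421), but had 0.664 with those weights and an estimated correlation. By edgeR's test adjusted over the list alone 9 members passed, 6 higher and 3 lower, and 0 passed over all genes. Arntl, the core activator BMAL1, stood at 12.2 ± 0.978 CPM in control and 2.58 ± 1.45 in Treg (−2.24 ± 0.37), and its partner genes Npas2 and Clock had −1.84 and −0.80. Per3 stood at 21.3 ± 4.88 and 59.0 ± 9.47 CPM (1.47) and Hlf, a clock-driven output factor, at 7.74 ± 2.24 and 27.0 ± 6.29 (1.80). Without control replicate 3, edgeR called 5 clock genes over all genes, 3 higher and 2 lower, and the list ranked higher (camera adjusted p = 0.00981; adjusted p = 0.654 with an estimated correlation).

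**Figure D4:**
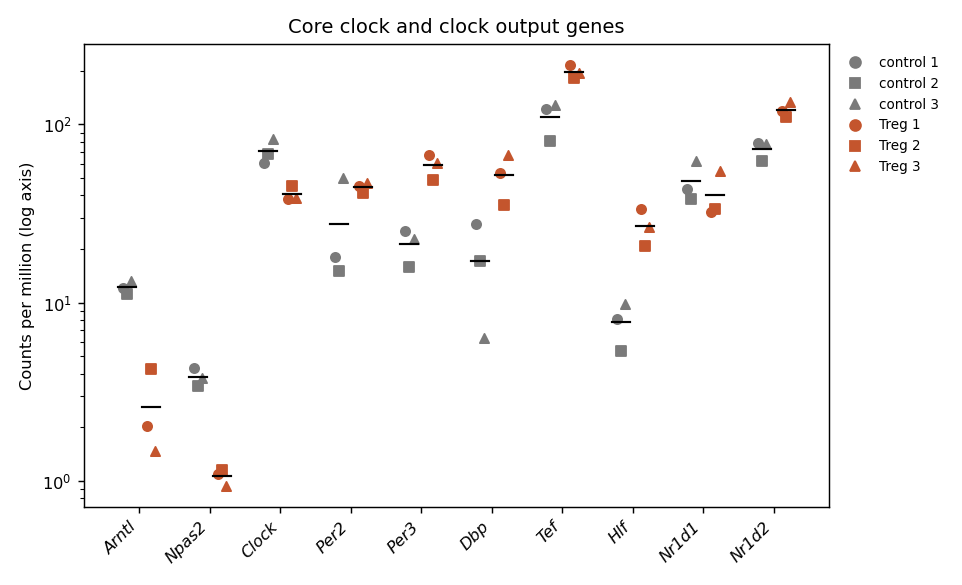
CPM on a log axis for 10 clock and clock output genes; points are libraries (grey control, orange Treg, symbol by replicate number) and black bars are group means. Arntl lies at 12.2 against 2.58 CPM and Npas2 at 3.82 against 1.06 CPM as group means, while Per3 and Hlf lie higher in the Treg libraries.

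The remaining 21 lists did not pass by camera at its preset correlation. Nuclear-encoded oxidative phosphorylation genes had an adjusted p of 0.0534 and a median of 0.09, resting fibroblast markers 0.0607 and 0.34, fatty acid oxidation 0.0693 and 0.17, Schwann, epicardial and mesothelial markers 0.0693 and 0.48, and pericyte and smooth muscle markers 0.071 and 0.17. Some of these medians hung on single libraries: oxidative phosphorylation and fatty acid oxidation had −0.05 and −0.02 without Treg replicate 2. They had 0.20 without Treg replicate 3 and 0.41 without control replicate 3, in that order, and resting fibroblast markers had 0.17 without control replicate 3. Complement and coagulation genes had an adjusted p of 0.0904, angiogenic and hypoxia genes 0.0986, oxidative stress genes 0.12, adipocyte markers 0.121, cell cycle genes and neutrophil markers 0.123 each, and apoptosis genes 0.131. Immediate early genes had 0.309, adult cardiomyocyte contraction genes 0.414, monocyte markers 0.45, erythroid genes 0.479, skeletal muscle genes 0.67, glucocorticoid response genes 0.685, heat shock and unfolded protein genes 0.899, endothelial markers 0.928 and mitochondrially encoded genes 0.946. Other settings with all 6 libraries called some of them: oxidative phosphorylation genes with ranks (0.0122) and at a mean of at least 1 CPM (0.0482), neutrophil markers, lower, with ranks (0.0211), and, with sample quality weights, resting fibroblast markers (0.0222) and fatty acid oxidation genes (0.000895). With one library left out, 11 of these lists passed at least once, given here at their smallest camera adjusted p. Without control replicate 1, cell cycle genes and neutrophil and monocyte markers ranked lower (2.72e-05, 0.00555 and 0.0198) and resting fibroblast markers higher (0.00592). Without Treg replicate 3, oxidative phosphorylation genes and pericyte markers ranked higher (4.78e-05 and 0.027) and apoptosis genes lower (0.0423). Fatty acid oxidation genes ranked higher without control replicate 3 (5.96e-05) and complement genes without control replicate 2 (0.0389). Without Treg replicate 1, Schwann, epicardial and mesothelial markers and immediate early genes ranked higher (0.0158 and 0.0163). Without both replicates 3, glucocorticoid response genes ranked higher (0.016), opposite to their direction with all 6 libraries. With an estimated correlation 0 lists passed in any of the 6 omissions (smallest camera adjusted p = 0.526) or without both replicates 3 (0.591). The same held with all 6 libraries at a mean of at least 1 CPM (0.684) and with sample quality weights (0.617).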

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

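The analyses with sample quality weights, with protein-coding genes only, with DESeq2 without control replicate 3, and without both control replicate 3 and Treg replicate 3 were chosen after the data were seen; the rest were fixed beforehand. The number of genes past the threshold, 0 by edgeR, stayed at 0 with RLE or upper-quartile scaling, a mean of at least 1 CPM, limma-voom, edgeR's newer dispersion method, removal of mitochondrially encoded genes, a log2 fold change of at least 1 and protein-coding genes only. It was 38 with no filter on low counts, 82 at an adjusted p under 0.1, 650 with DESeq2 and 264 with limma-voom and sample quality weights, which gave control replicate 3 a weight of 0.19 against 0.85 to 2.53 for the others. Leaving out one library gave 0 to 230 genes with edgeR, the 230 coming only from omission of control replicate 3 and 0 from each of the other 5 omissions; DESeq2 without control replicate 3 called 1052, and edgeR without control replicate 3 and Treg replicate 3 called 119. Of the 82 genes under an adjusted p of 0.1, 76 were among the 230, and so were 169 of the 650 called by DESeq2. Omitting control replicate 3 lowered the biological coefficient of variation from 0.237 to 0.158; the cause of the gap between DESeq2 and edgeR, and of the 38 calls without a filter, was not tested. The number of lists past the threshold, 11, became 0 with an estimated correlation and 0 with fry, 10 with ranks (2 gained and 3 lost), and 10 to 19 when one library was left out, the highest without Treg replicate 3. The list-alone count of 92 members became 90 with RLE scaling. With the replicate number as a block, 0 genes and 14 lists passed. Matrix glycoproteins (camera adjusted p = 0.0171), resting fibroblast markers (0.0367), oxidative phosphorylation genes (0.0367) and neutrophil markers (0.0343) were gained and glycolysis genes (0.0688) lost. With the block and an estimated correlation 0 lists passed (smallest camera adjusted p = 0.761). Deviations of same-numbered libraries from their group means correlated at −0.142, −0.236 and 0.042, and control replicate 1 correlated best with Treg replicate 2 (0.309). The replicate numbers thus gave no sign of pairing, which 3 libraries per group are too few to exclude. Values near 0 changed sign, for causes that were not tested: Nppa was 0.11 with limma-voom, 0.07 with the replicate block and −0.89 to 0.46 with libraries left out, Foxp3 was −0.04 to 0.10, and Myh6 was −0.02 to 0.43 (−0.03 with DESeq2 without control replicate 3). Myl4 was −0.51 to 3.33, below 0 only without Treg replicate 3, where its level was high. Some lists changed direction and did not pass when they did, given as adjusted p: macrophage markers with fry (0.959), without control replicate 2 (0.146) and without Treg replicate 2 (0.827), T cell markers at a mean of 1 CPM (0.731), cytokines without control replicate 3 (0.438) and without both replicates 3 (0.932), TGF-beta genes without Treg replicate 1 (0.938) and atrial genes without both replicates 3 (0.927). Over all omissions, in either direction, these p were 0.038 to 0.866 for macrophage markers, 0.0528 to 0.932 for cytokines, 0.0217 (without both replicates 3, where an estimated correlation gave 0.591) to 0.938 for TGF-beta genes and 0.00137 to 0.927 for atrial genes.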

Other observations

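The tests of depth, macrophage share and labelling of control replicate 3, of the time of day, and of macrophage and dendritic cell content were chosen after the results were seen. Without control replicate 3, the genes with the smallest p, taken by the same rule, were in part not those named above. Serpinb9b, a serine protease inhibitor, stood at 41.29 and 37.66 CPM in the 2 remaining controls and at 3.68 to 4.02 in the Treg libraries (log2 fold change −3.36, edgeR adjusted p = 4.14e-05), Pak3, a p21-activated kinase, had −2.58, Myl9, a smooth muscle myosin light chain, −2.27, and Fbn2, a fibrillin of developing matrix, −2.39. Among those higher were Per2 (1.42), Zbtb16 (1.32), the splicing regulator Rbfox1 (1.44), Asb15 (1.37) and Icosl, the ligand of the T cell costimulator ICOS, at 11.41 to 12.43 CPM against 4.58 and 5.10 (1.29). With all 6 libraries these 9 genes had the same sign, but Per2, Zbtb16 and Icosl had 0.68, 0.89 and 0.59, as control replicate 3 lay with the Treg libraries or near them (50.02, 81.63 and 14.07 CPM).

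Some members of lists that did not pass also separated the groups, by edgeR's test adjusted over the list alone. In the complement and coagulation list 4 genes were higher and 1 lower, with 0 over all genes: C3, the central complement component, stood at 125.5 ± 39.7 CPM in control and 263.5 ± 31.6 in Treg (log2 fold change 1.07), C1s1 had 0.83, C4b 0.79, and the thrombin receptor gene F2r −0.75. Jun and Egr1, immediate early transcription factors, had 1.15 and 0.95, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, 1.02.

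No gene passed edgeR's threshold in any of the 10 splits of the 6 libraries into 3 and 3 (10 of 10 as large, real value 0, highest other 0). With DESeq2 the real split gave 650 genes and the highest other 53, so 1 of 10 splits was as large; at an unadjusted p under 0.05 by edgeR the real split gave 2873 and the highest other 1109. For lists by camera the real split gave 11 and the highest other 21, and 10 of 10 splits were as large. With 10 splits the share cannot fall under 0.05. The matrix protease, class II and ion channel lists had a smaller p in the real split than in each of the other 9. The margins were narrow (camera p 8.29e-06 against 2.54e-05, 1.55e-05 against 3.09e-05 and 1.88e-05 against 2.25e-05). The angiogenic list and the Schwann, epicardial and mesothelial list, which did not pass, also came first. Chance puts a list first in 1 of 10 cases, and 40 were tested, so this does not set these lists apart. The interferon list had a smaller p in 1 other split (8.95e-20 against 5.36e-15), and the collagen list in 4.

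The departure of control replicate 3 from the other 5 libraries was weighed against 3 technical explanations and a different share of macrophages. Its total was 0.97 of the median of the others, which argues against depth, and across genes its difference from the other controls had a Spearman correlation of 0.004 with exonic length, which argues against a length bias from degraded RNA. A Treg library under a control label was examined on 230 genes chosen by p without it and 1 Treg library, in 3 choices. In control replicate 3, 69.1% to 75.2% of them lay nearer to the other controls than to the other Treg libraries. In the left-out Treg library this share was 5.22% to 16.1%. This comparison was chosen after an earlier one had missed its bound. On the 230 genes called without control replicate 3 alone, the share was 73%, under a bound of 80% set first. Control replicates 1 and 2, each left out with 230 genes of smallest p, also missed that bound, at 47.8% and 76.5%. A library labelled control can thus lie nearer the Treg libraries at the majority of such genes. The Treg libraries, each left out in this way, had 7.39% to 12.6%. At such genes control replicate 3 was thus unlike each Treg library, but a rule set after a missed bound does not settle its label. Of the macrophage markers, 3 lay over 2-fold above all other libraries (Pf4, Lyve1, Arg1) and 2 over 2-fold below (Cx3cr1, Ms4a7), too few for the bound set on moving apart. The list's median in control replicate 3, −0.037, lay within the range of the other libraries (−0.466 to 0.369). The markers thus showed no shift as a set, but another share or state of macrophages in that piece of tissue stays open.

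Lower Arntl, Npas2 and Clock with higher Per3, Tef and Hlf in the Treg libraries is a pattern that collection at another time of day may produce. Of 11 clock genes with a phase assigned from general knowledge, 10 differed to the side this predicts, and Nr1d1 (−0.25 ± 0.26) did not; the labels give no collection times, so it cannot be told apart from a change in the clock with treatment. Control replicate 3 alone is argued against, since Arntl had a log2 fold change of −2.18 without it.

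Control replicate 3 alone is argued against as the source of the higher interferon genes in the Treg libraries. Their median log2 fold change was 0.75 without it and 0.90 with all 6 libraries. The list's camera adjusted p without it was 3.6e-12 (1.17e-21 to 1.62e-09 over the 6 omissions of a library), but 0.654 with an estimated correlation. Class II genes differed less without that library, with a median of 0.97 against 1.51. Their camera adjusted p was then 0.000156, and 0.654 with an estimated correlation, so its part in their difference is not settled. For the class II genes, with all 6 libraries, more macrophages are argued against. The highest log2 fold change among C1qa, C1qb, C1qc, Csf1r and Mrc1 was 0.26, while the lowest of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 was 2.06. The interferon genes were not compared in this way. Nor was the comparison repeated without control replicate 3, whose omission moved the class II median from 1.51 to 0.97. More dendritic cells may contribute: 2 of 6 markers (Cd209a and Flt3) were at least 1 higher on the log2 scale while Zbtb46, Clec9a, Xcr1 and Irf8 were not, which leaves this open. A treatment effect stays open too, as untested, and an estimated correlation between genes removed both lists' calls.

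Cd3e was at 465 counts in control replicate 3 and 12 to 82 in the other libraries while Cd3d was at 0 to 3. Trac was at 5, 4 and 0 counts in the controls and 7, 7 and 13 in the Treg libraries, too few to test.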
